A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

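Splenic mouse CD4 T cells were measured by bulk RNA-seq in 6 libraries, 3 labelled wild type and 3 labelled Ifnar1-/-, each after 24 h with anti-CD3 and anti-CD28 at 2 µg/ml each, per the labels. Human naive and memory CD4 and CD8 T cells from blood of healthy donors were measured by droplet single-cell RNA-seq (10x Chromium v3) at 0, 12 and 24 h, 1 library per population and time. Per the labels the human cells were enriched by negative selection and sorted on CD45RA and CD45RO, CD4 cells were given anti-CD3 at 2 µg/ml and CD8 cells at 0.25 µg/ml, both with anti-CD28 at 2 µg/ml, and the number of donors is not stated. No sample fell outside these groups.

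The deposited mouse table holds counts per gene symbol, made by the authors with Trim Galore 0.6.7, STAR 2.7.8a on GRCm38 (mm10) and featureCounts (Subread 2.0.3) after FastQC 0.11.9. A second deposited mouse table holds CPM after TMM scaling, made by the authors with edgeR in R 4.1.0 for 12714 of the 24421 genes with a filter that is not stated. For the 11036 genes that could be compared it differed from CPM recomputed from the counts by a median of 0.228%. The deposited human matrices hold UMI counts per gene and barcode, already called as cells. For these the labels name Cell Ranger 2.1.0 and Seurat, while the matrix headers name Cell Ranger 3.0.2, and the human genome build is not given. The mouse table carries symbols without identifiers and the human files carry Ensembl identifiers with symbols. No mouse annotation was at hand, so no mouse position is given, and the neighbours of Ifnar1 were taken from the order of coding genes on the human reference (GRCh38).

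Mouse counts were analysed in R 4.3.3 with edgeR 4.0.16: genes kept by filterByExpr (12735), TMM factors (0.994 to 1.005), a quasi-likelihood fit of genotype, and Benjamini-Hochberg adjusted p with a threshold of 0.05. Values per gene are TMM CPM with mean and SD of 3 libraries, and SE of a log2 difference is that of the fit. Depth ran from 36300493 to 231331609 counts per library, and the 10 most abundant genes took 4.66 to 4.80% of each. On simulated counts with these depths and this dispersion the fit recovered 86 of 100 genes changed 2-fold and 99 of 100 changed 4-fold. It made 10 false calls among 12632 genes. Simulated genes varied independently, without structure shared between libraries, and the changed ones were not of low expression. These shares are therefore not the power of the fit on the real libraries. Gene lists, 28 in all, were written before the data were examined, as were the comparisons, the thresholds, the alternatives not marked as later, and the rule for named genes. The 26 lists with at least 3 tested members were compared with all other genes by camera of limma 3.58.1 with its preset correlation of 0.01, beside camera with an estimated correlation. Fry tested whether the genes of each list move on balance one way, with no comparison with other genes. Each test was adjusted over the 26 lists.

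Human barcodes were kept with at least 500 detected genes and at most 10% mitochondrial UMIs, which left 33.6 to 92.9% of barcodes per library (778 to 6164 cells). Over the 12 libraries 4.88 to 65.4% of barcodes were above the mitochondrial limit, most in the resting CD8 libraries. UMIs were summed over the kept cells and scaled to CPM of all kept UMIs (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). A gene counted as higher or lower at a ratio of at least 2 with 1 CPM added and at least 50 CPM in the higher library, a rule of size and not a test, since each group held 1 library. Kept UMIs per library ran from 5592186 to 88368037, and CPM have 95% exact Poisson intervals. A list member counted as measured at 10 CPM in either library and as higher or lower at 1.5-fold, and the list's median log2 ratio was placed among 10000 random lists matched in 20 bins of expression. On simulated lists 4 of 100 without a shift fell outside the middle 95% and 98 of 100 shifted by 1 on the log2 scale lay above it. The simulated lists were drawn gene by gene from the same genes as the random lists, so the first result was set by construction. Members of real lists vary together, so a percentile gives a place among random lists and no error rate. Shares of cells with a UMI were counted after thinning each cell with enough UMIs to 2000, with exact binomial intervals, and the naive CD4 shares of GZMB and IFNG stand beside the others. Free RNA in a library comes from its own cells, and no sorted library was known to hold cells that lack these genes. Its share was therefore not measured for any of the 7 genes.

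Clusters were made per library with scanpy 1.11.5, igraph 0.11.9 and leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5) and named when at least 3 markers of a cell type stood among its leading 30 genes at 1.5-fold or more, at least 1 of them among the leading 10. Doublets were scored with Scrublet, whose own threshold failed in these libraries (under 1% of cells called in 10 of them and over 50% in 1). The highest scores at 0.8% per 1000 barcodes were therefore left out of the clusters instead (1.80 to 5.31% per library), a choice made after the scores were seen.

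Named genes followed a fixed rule. In the mouse they are Ifnar1, the 10 largest changes per direction among called genes whose genotypes did not overlap and whose average log2 CPM was at least 1, and up to 4 members per list with the smallest p. In the human time courses they are the 10 largest ratios per direction and up to 4 members per list with the largest mean ratio at 24 h, and between populations up to 6 per direction with 5 genes fixed beforehand, the coreceptors and CCR7 among them. CD69, GZMB, IFIT3, IFNG, IL2, IL2RA and ISG15 were fixed for the shares. Only the genes of these sets that carry a comparison are printed, and variable, joining and diversity segments of receptors, mitochondrial genes, clone-named loci and genes that vary between people in presence were never named.

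Alternatives tried on the mouse data were DESeq2 1.42.0, RLE size factors, no low-count filter, replicate number as a block, each library left out and limma-trend on the deposited CPM. Added after the data were seen were a covariate for the libraries with Xist above 100 CPM, the deepest library thinned, and a fit without the 2 Ifnar1-/- libraries with Lyz2 above 3 CPM. On the human data they were no barcode filter, a strict one (at least 1000 genes, at most 5% mitochondrial UMIs), doublets left out, TMM scaling, the mean of per-cell CPM, a minimum of 10 CPM, a pseudocount of 10, a Leiden resolution of 1.0, clusters with doublets kept, and other thinnings. Added after the data were seen were a mitochondrial limit of 20% and ratios centred on the median gene. Intronic reads, isoforms and receptor sequences could not be had from these tables and were left out.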

Results

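The series holds 6 bulk RNA-seq libraries of mouse T cells and 12 droplet single-cell RNA-seq libraries of human T cells. The mouse libraries came from CD4 T cells of the spleen, 3 labelled wild type and 3 labelled Ifnar1-/-, harvested after 24 h with antibodies to CD3 and CD28 at 2 µg/ml. Ifnar1 codes for a chain of the receptor for type I interferons, the antiviral cytokines. Wild type replicates 1, 2 and 3 had 55879706, 39473382 and 231331609 counts. Ifnar1-/- replicates 1, 2 and 3 had 36300493, 50271226 and 43003032. The human libraries covered 4 populations sorted from blood of healthy donors, naive (CD45RA+) and memory (CD45RO+) CD4 and CD8 T cells. They were taken at 0, 12 and 24 h of the same kind of stimulation, with 1 library per population and time. Naive CD4 libraries kept 4462, 4639 and 6164 cells with 23496885, 32517315 and 62609724 UMIs at 0, 12 and 24 h. Memory CD4 libraries kept 3015, 3609 and 5342 cells with 18613388, 36125877 and 88368037 UMIs. Naive CD8 libraries kept 1083, 2139 and 4593 cells with 6744482, 20794916 and 74720616 UMIs. Memory CD8 libraries kept 778, 2258 and 5061 cells with 5592186, 25276296 and 56156808 UMIs.

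The mouse comparison asked which transcripts differ between stimulated CD4 T cells labelled Ifnar1-/- and those labelled wild type. Itsn1, an endocytic scaffold gene, stood at 16.9 ± 1.47 TMM CPM (mean ± SD, n = 3) in the libraries labelled Ifnar1-/- and at 3.43 ± 0.634 in wild type, a log2 difference of 2.32 (SE 0.15, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00626). Abi3, which codes for an adaptor of the actin cytoskeleton, fell from 9.98 ± 0.775 CPM in wild type to 3.18 ± 0.653 (log2 -1.65, SE 0.15, edgeR adjusted p = 0.0492). Edn1, the gene of a vasoconstrictor peptide, fell from 12.9 ± 1.22 to 4.86 ± 0.936 CPM (log2 -1.41, SE 0.15, edgeR adjusted p = 0.0492). Both other calls had low counts, lay outside the rule for named genes and are named after their values were seen. Mx2, an interferon-induced antiviral GTPase, stood at 0.0826 ± 0.0240 CPM against 0.708 ± 0.0885 in wild type (log2 -3.03, SE 0.32). Btg3, an antiproliferative gene, stood at 0.636 ± 0.0238 CPM against 0.0757 ± 0.0290 (log2 3.06, SE 0.32), and edgeR gave each an adjusted p of 0.0492. For each of these 5 genes the 3 libraries labelled Ifnar1-/- lay on one side of the 3 wild type libraries.

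Ifnar1 itself read 48.5, 76.7 and 50.9 CPM in replicates 1, 2 and 3 of the libraries labelled Ifnar1-/- and 59.9, 57.0 and 65.0 in wild type (log2 -0.05, SE 0.17, edgeR adjusted p = 0.907). Leaving out 1 library at a time gave log2 values from -0.29 to 0.07, so the Ifnar1 level did not part the genotypes. A count over the whole gene does not show which exons or sequence its reads carry, and this level does not check the labels. In all, 2 of 12735 genes rose and 3 fell, with 1092 higher and 879 lower at an unadjusted p under 0.05. The genotypes did not overlap for 2586 genes (20.3%), where the mean over all splits of the libraries is 10%. Genes vary together, so this excess is no test of genotype. Other splits that kept Ifnar1-/- replicates 2 and 3 together had 1368, 1099 and 1170 genes at an unadjusted p under 0.05 by edgeR. The remaining splits had 60 to 310, and the genotype split 1971. The count of calls depended on single libraries. It was 1 higher and 0 lower without wild type replicate 1, 2 and 0 without wild type replicate 2 and 1 and 1 without wild type replicate 3. It was 1074 and 959 without Ifnar1-/- replicate 1, 1 and 0 without replicate 2 and 1 and 2 without replicate 3. DESeq2 called 157 genes higher and 122 lower, and every other setting run on all 6 libraries called at most 2 higher and 5 lower. The Itsn1 call was kept in each setting except without wild type replicate 1 (edgeR adjusted p = 0.0628), with a log2 difference from 2.02 to 2.45. The calls of Abi3, Edn1, Mx2 and Btg3 were each lost without any single wild type replicate and without Ifnar1-/- replicate 2 (edgeR adjusted p from 0.103 to 0.365). Without Ifnar1-/- replicate 3 Abi3 kept its call (edgeR adjusted p = 0.0198) and Edn1, Mx2 and Btg3 lost theirs (0.234 each). Without replicate 1 all 4 kept theirs (edgeR adjusted p from 0.00168 to 0.00599). Edn1, Mx2 and Btg3 also lost their calls with the replicate block, the Xist covariate and limma-trend on the deposited CPM (edgeR or limma adjusted p from 0.0521 to 0.141), where Abi3 kept its call. With the deepest library thinned all 4 lost theirs (edgeR adjusted p from 0.0522 to 0.0725). Leaving out both Ifnar1-/- replicates 2 and 3 left 1 Ifnar1-/- library, which is then assumed to vary like the wild type ones, and edgeR called 3 genes higher and 10 lower. Itsn1, Abi3 and Edn1 were among them (edgeR adjusted p = 0.00533, 0.00331 and 0.0321) and Mx2 and Btg3 were not (0.156 and 0.164).

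**Figure D1:**
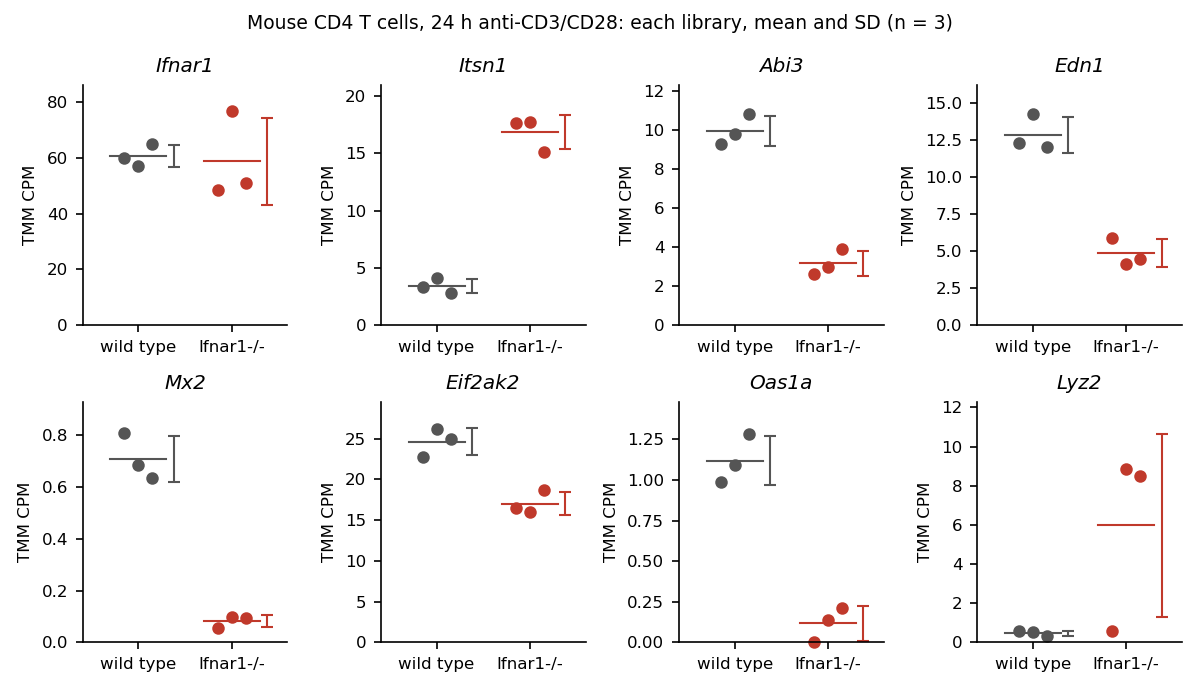
TMM CPM of 8 genes in each mouse library (points), with the mean (horizontal line) and SD (bar beside the points) of 3 libraries per genotype, wild type in grey and Ifnar1-/- in red. Ifnar1 overlaps between the genotypes, Itsn1 is higher and Abi3, Edn1, Mx2, Eif2ak2 and Oas1a are lower in all 3 Ifnar1-/- libraries, and Lyz2 is above 8 CPM in Ifnar1-/- replicates 2 and 3 alone.

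Genes of the type I interferon response were lower in the libraries labelled Ifnar1-/- for a part of the list. Of 62 tested members, 12 fell and 0 rose when adjusted over the list alone, and 1, Mx2, passed over all genes. Eif2ak2, the gene of an RNA-sensing kinase that halts translation, stood at 17.0 ± 1.44 CPM against 24.6 ± 1.69 in wild type (log2 -0.53, SE 0.08). Oas1a, a sensor of double-stranded RNA, stood at 0.116 ± 0.107 against 1.12 ± 0.150, and the antiviral GTPase Mx1 at 0.240 ± 0.160 against 1.20 ± 0.251. Their edgeR adjusted p over all genes were 0.147, 0.233 and 0.287, and each was lower in all 3 libraries. As a whole the list was mixed, with 34 members lower and 28 higher, a median log2 of -0.07 and a mean of -0.22. Camera with its preset correlation placed it below other genes (adjusted p = 0.00609), and at adjusted p = 0.784 with an estimated correlation it made no call. Fry, which tests whether the genes of a list move on balance one way and compares them with no other genes, gave adjusted p = 0.562. In Ifnar1-/- replicates 2 and 3, 14 members were above and 0 below all other libraries. Over all genes 22.4% were above and 21.4% below, so the 14 above were no excess. The monocyte and macrophage marker Lyz2 stood at 8.85 and 8.49 CPM there against 0.324 to 0.578 in the other 4. Without Ifnar1-/- replicate 1 the list turned upward (camera adjusted p = 0.980), and without replicates 2 and 3 it stayed downward (camera adjusted p = 3.74e-39, adjusted p = 0.415 with an estimated correlation).

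Guanylate-binding proteins and class I antigen presentation genes showed no call, with 20 of 28 members higher (median log2 0.09, camera adjusted p = 0.215). Within that list Irgm1 was at 215.6 ± 18.8 CPM against 255.9 ± 4.99 in wild type and Gbp6 at 56.3 ± 8.06 against 71.2 ± 3.04, both lower in all 3 libraries. The 6 tested interferon ligands and receptors, Ifnar2 among them (log2 0.11), had no call either (4 higher, camera adjusted p = 0.155). Both lists passed without Ifnar1-/- replicate 1, upward, at camera adjusted p = 0.000732 for the antigen presentation list and 0.0167 for the ligands and receptors (adjusted p = 0.636 and 0.402 with an estimated correlation). Without replicates 2 and 3 the antigen presentation list was below other genes instead (camera adjusted p = 5.89e-10, adjusted p = 0.738 with an estimated correlation).

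Cell cycle and sterol genes were lower in the libraries labelled Ifnar1-/-, and genes of memory, cytotoxic and quiescent T cells were higher, mostly through replicates 2 and 3. All 31 DNA replication genes were lower (median log2 -0.19). Among them were the nucleotide enzymes Tk1 (58.7 ± 9.25 CPM against 76.2 ± 4.55) and Tyms, which read 97.9, 66.1 and 81.2 CPM against 104.4 to 108.6 in wild type. Of 29 mitosis genes 28 were lower (median log2 -0.30), Aurkb, a kinase of chromosome segregation, at 88.3, 58.3 and 76.0 CPM against 92.0 to 99.7. Sterol synthesis and uptake genes were lower in 22 of 24 (median log2 -0.15), Fdft1 at 56.2 ± 3.89 against 67.7 ± 2.84 CPM. Camera with its preset correlation called these lists down at adjusted p = 6.40e-13, 1.51e-10 and 4.15e-07, but each at adjusted p = 0.701 with an estimated correlation. By edgeR 0 members of each passed when adjusted over the list alone. In Ifnar1-/- replicates 2 and 3, 31 of 31, 23 of 29 and 21 of 24 members lay below all other libraries, beside the Lyz2 level of 8.85 and 8.49 CPM. Without these 2 libraries the sterol call was lost (camera adjusted p = 0.271), while the DNA replication and mitosis lists stayed down (camera adjusted p = 3.65e-05 and 0.00175, adjusted p = 0.448 and 0.898 with an estimated correlation).

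Memory state genes were higher in 21 of 23 (median log2 0.72), and 12 rose and 1 fell when adjusted over the list alone. Cytotoxicity genes were higher in 16 of 17 (median log2 0.60, 1 up and 1 down over the list alone). The granzyme Gzma read 4.90, 17.3 and 19.6 CPM against 2.01 to 5.65, and the protease inhibitor Cst7 was lower at 62.6 ± 4.43 against 81.4 ± 3.32. Quiescence genes were higher in 22 of 28 (median log2 0.23). The transcription factor Klf2 read 18.4, 61.3 and 30.4 CPM against 12.8 to 18.4. Cytokine and chemokine genes were higher in 22 of 30 (median log2 0.34), Ifng, the type II interferon, at 116.9, 493.9 and 783 CPM against 48.9 to 151.9. T helper lineage factors were higher in 19 of 25 (median log2 0.30), Prdm1 at 4.30, 12.6 and 14.0 CPM against 3.48 to 4.76. Camera with its preset correlation called these 5 lists up at adjusted p = 1.28e-05, 0.000226, 0.00258, 0.0247 and 0.0110, each at adjusted p = 0.701 with an estimated correlation. Monocyte and macrophage markers moved with them, 9 of 9 being higher (median log2 1.89, camera adjusted p = 1.80e-06, adjusted p = 0.701 with an estimated correlation). All 9 passed when adjusted over the list alone and 0 over all genes, and Csf1r read 0.275, 1.21 and 1.24 CPM against 0.138 to 0.251. NK cell markers were higher in 6 of 7 (camera adjusted p = 0.0132, adjusted p = 0.701 with an estimated correlation), Ncr1 at 0.633, 1.37 and 1.36 CPM against 0.190 to 0.304. Without Ifnar1-/- replicates 2 and 3 the monocyte list kept its call (camera adjusted p = 0.00282, adjusted p = 0.898 with an estimated correlation) and the 6 other lists lost theirs. The memory, cytotoxicity, cytokine and T helper lists turned downward with camera adjusted p of 0.797, 0.846, 0.282 and 0.792. The quiescence and NK lists had camera adjusted p of 0.792 and 0.335. Single left-out libraries ended the cytokine call (camera adjusted p = 0.175 without wild type replicate 1, 0.0848 and 0.129 without Ifnar1-/- replicate 2 or 3). They also ended the quiescence and NK calls (0.107 each without replicate 2) and the T helper call (0.0640 without replicate 3).

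Chaperones and ER folding genes were slightly higher in 28 of 30 (median log2 0.06, camera adjusted p = 5.72e-05, adjusted p = 0.701 with an estimated correlation). Hsp90b1 stood at 884 ± 65.0 CPM against 771 ± 22.1, and the call was kept without Ifnar1-/- replicates 2 and 3 (camera adjusted p = 6.77e-05, adjusted p = 0.898 with an estimated correlation). Cytosolic ribosomal proteins were higher in 35 of 49 (median log2 0.04, camera adjusted p = 0.0245, adjusted p = 0.825 with an estimated correlation). The ribosomal call was lost without wild type replicate 2 or 3 (camera adjusted p = 0.0921 and 0.767) and without Ifnar1-/- replicate 2 or 3 (0.393 and 0.0640), and with the replicate block and the Xist covariate (0.0912 and 0.0506). It turned downward without both Ifnar1-/- replicates 2 and 3 (camera adjusted p = 0.139). Lists without a call were T cell activation receptors (17 of 30 higher, camera adjusted p = 0.975), glycolysis (12 of 21, 0.497), oxidative phosphorylation (27 of 40, 0.515) and eicosanoid metabolism (17 of 25, 0.155). Others were ribosome biogenesis and MYC targets (15 of 33, 0.869), ATF4 targets (16 of 28, 0.689) and NF-kB targets (13 of 20, 0.0578). In the activation list Crtam, an adhesion receptor, stood at 22.9 ± 1.74 CPM against 35.5 ± 2.71 and Cd83 at 24.1 ± 2.33 against 33.9 ± 3.28, the 2 members that fell over the list alone. Its camera direction (down) and median log2 (0.09) differed in sign. Glycolysis also had a median log2 of 0.01 beside a mean of -0.02 and a downward camera sign. For plasmacytoid dendritic cell markers (4 of 6 lower, camera adjusted p = 0.398) the median was -0.07 and the mean 0.05. Without Ifnar1-/- replicate 1 the eicosanoid and NF-kB lists passed upward (camera adjusted p = 0.0159 and 0.00203, adjusted p = 0.355 and 0.245 with an estimated correlation). The NF-kB list also passed with the replicate block and a thinned deepest library (camera adjusted p = 0.0224 and 0.0486, adjusted p = 0.648 and 0.713 with an estimated correlation). Glycolysis passed downward without Ifnar1-/- replicate 3 (camera adjusted p = 0.0248, adjusted p = 0.771 with an estimated correlation). The ribosome biogenesis list passed upward without both Ifnar1-/- replicates 2 and 3 (camera adjusted p = 0.000239, adjusted p = 0.898 with an estimated correlation). B cell markers were higher in 11 of 12 (camera adjusted p = 0.199), platelet markers in 3 of 3 (0.0521), and the CD4 and CD8 coreceptors in 3 of 3 (0.306). The B cell list passed without Ifnar1-/- replicate 2, with the replicate block and with the Xist covariate (camera adjusted p = 0.00904, 0.00581 and 0.00289, adjusted p = 0.716, 0.648 and 0.587 with an estimated correlation). Cd4 stood at 414 ± 41.4 CPM against 402.3 ± 8.59 and Cd8a at 2.52 ± 1.53 CPM against 1.88 ± 0.558. The platelet list, with 7 tested members then, passed without wild type replicate 1, 2 or 3 and without Ifnar1-/- replicate 1 (camera adjusted p = 0.000353, 0.000147, 0.000129 and 2.42e-06, adjusted p = 0.767, 0.680, 0.719 and 0.226 with an estimated correlation). With 3 members it passed under RLE size factors (camera adjusted p = 0.0476), the Xist covariate (0.0111), the replicate block (0.000973) and a thinned deepest library (0.0273). With an estimated correlation these 4 were at adjusted p = 0.680, 0.587, 0.543 and 0.702. Of the erythroid markers 2 were measured, Alas2 and Car1, at 0.920 ± 0.580 and 3.37 ± 2.65 CPM against 0.357 ± 0.159 and 0.636 ± 0.309. Of the gamma delta T cell markers 0 were tested. With an estimated correlation camera called 0 lists in each setting in which lists were run. The labels do not say whether the libraries came from separate animals, so each p measures the spread between these 6 libraries.

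The human time courses asked which transcripts change as each T cell population goes from rest to activation. In all 4 populations the genes of resting T cells were lower and the receptors and factors of activated T cells higher at both times. The quiescence factor KLF2 (ENSG00000127528) went from 1018, 1061, 805 and 733 CPM at 0 h in naive CD4, memory CD4, naive CD8 and memory CD8 cells to 23.7, 4.40, 24.9 and 2.96 at 24 h. IL7R, the receptor of the survival cytokine IL-7, averaged 1187 CPM over the 4 populations at 0 h and 76.3 at 24 h, and PIK3IP1, a brake on PI3 kinase, 231 and 9.81. The costimulatory receptor TNFRSF9 (ENSG00000049249) went from 0.0851, 2.31, 0.445 and 1.61 CPM to 129.2, 115.7, 250.1 and 316. The transcription factors IRF8 and BATF3 went from means of 0.274 and 5.22 to 108.9 and 214.8. Of the quiescence list, 22 of 29, 20 of 28, 18 of 29 and 21 of 29 measured members were lower at 12 h and 27, 25, 25 and 26 at 24 h, with median log2 ratios from -0.77 to -2.16. Of the activation list, 23 of 24, 26 of 28, 23 of 26 and 27 of 30 were higher at 12 h, with medians of 4.27, 2.84, 3.86 and 3.30. At 24 h the medians were 4.08, 2.88, 3.57 and 2.93.

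Under the size rule (at least 2-fold with 1 CPM added, and at least 50 CPM in the higher library) 886 genes were higher and 404 lower at 12 h in naive CD4 cells, 801 and 344 in memory CD4, 380 and 164 in naive CD8, and 704 and 460 in memory CD8. At 24 h the counts were 1156 and 545, 1083 and 481, 1178 and 555, and 858 and 629. All 4 populations shared 282 higher and 96 lower genes at 12 h and 712 and 284 at 24 h. The higher genes made up 68.7, 70.0, 69.9 and 60.5% at 12 h and 68.0, 69.2, 68.0 and 57.7% at 24 h. TMM scaling gave 83.4, 83.2, 87.5 and 85.1% and then 81.4, 82.4, 84.7 and 86.3%. Median-centred ratios gave 48.8, 45.5, 59.0 and 47.3% and then 42.3, 40.6, 43.1 and 42.5%. A minimum of 10 CPM gave 42.7 and 42.0% in memory CD8 cells and 53.2 to 58.1% in the other populations. Barcodes with at least 1000 genes and at most 5% mitochondrial UMIs gave 57.3 and 56.6% in memory CD4, 46.2 and 42.1% in naive CD8 and 41.7 and 40.0% in memory CD8. This strict filter left 11, 13 and 61 naive CD8 cells at 0, 12 and 24 h and 18, 62 and 213 memory CD8 cells. Its CD8 values, here and below, therefore rest on few cells. The median log2 ratio of all measured genes was itself 0.39, 0.38, 0.12 and 0.22 at 12 h and 0.62, 0.54, 0.58 and 0.28 at 24 h. TMM scaling moved this shift to 0.43 to 1.08. With 1 library per population and time no difference was tested, and intervals and floors on human values cover counting error only. A gene with 0 UMIs in a library may stand at up to 0.0339 to 0.536 CPM there (3 counts). Percentiles place each list's median among 10000 random lists of genes matched for expression.

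**Figure D2:**
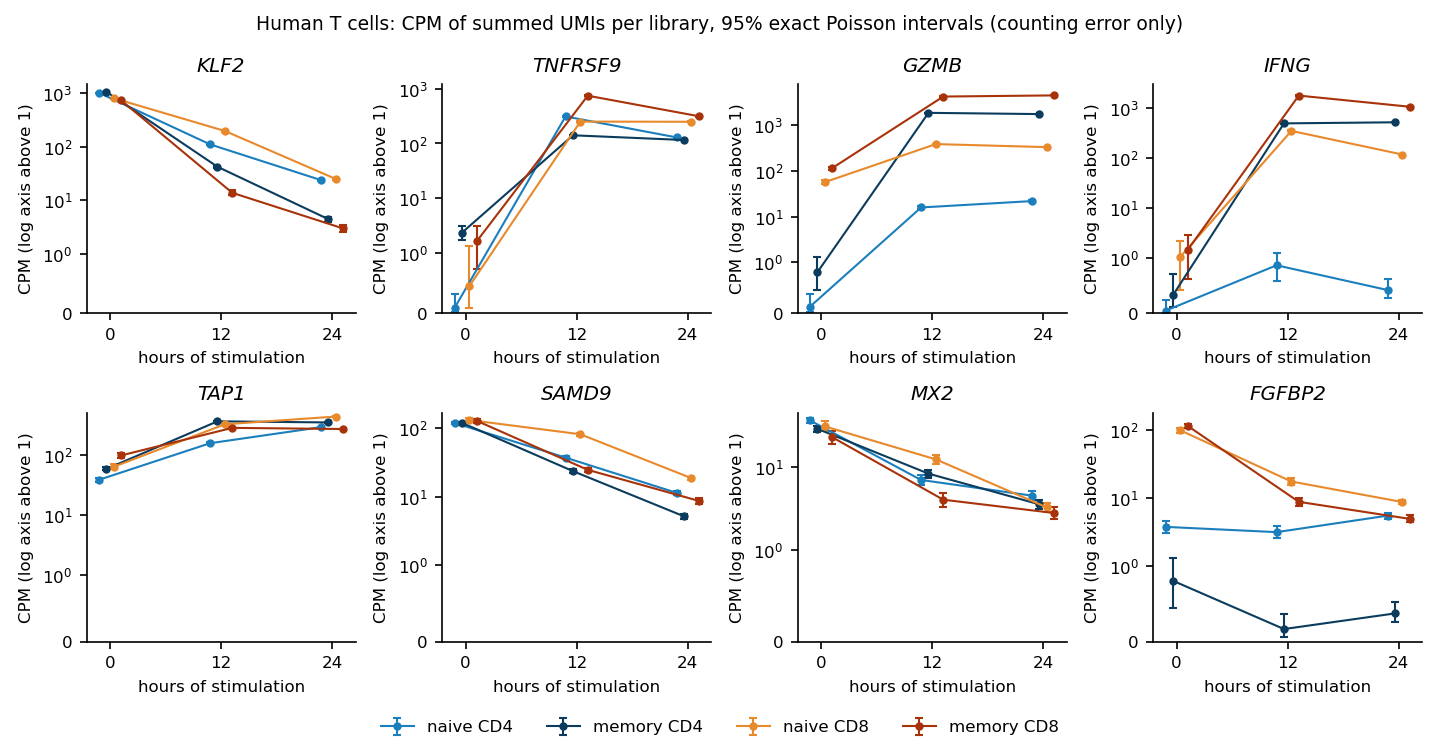
CPM of 8 genes in the 12 human libraries against hours of stimulation, on an axis that is logarithmic above 1 and linear below it, with 95% exact Poisson intervals as bars and 1 colour per population. KLF2, SAMD9 and MX2 are lower and TNFRSF9, GZMB and TAP1 higher at 24 h than at 0 h in all 4 populations. IFNG stays under 1 CPM in naive CD4 cells, and FGFBP2 is lower in both CD8 populations.

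Growth and biosynthesis genes were higher in every population by 12 h. Ribosome biogenesis and MYC target genes were higher in 32 of 32, 33 of 33, 30 of 32 and 32 of 33 measured members at 12 h in naive CD4, memory CD4, naive CD8 and memory CD8 cells (medians 2.24, 1.76, 1.32 and 1.84). The medians stayed at 2.21, 1.70, 2.18 and 1.69 at 24 h. ODC1, the first enzyme of polyamine synthesis, averaged 49.3 CPM at 0 h and 473 at 24 h, and NOP16 15.5 and 170.9. Amino acid transport and ATF4 targets had medians of 2.54, 2.05, 2.27 and 1.83 and then 1.98, 2.31, 2.52 and 2.32. The proline enzyme PYCR1 stood at means of 2.18 and 96.5 CPM and the tRNA synthetase WARS at 6.87 and 187. Glycolysis medians were 2.05, 1.0, 0.96 and 0.95 at 12 h and 2.00, 1.22, 2.09 and 1.09 at 24 h, with LDHA at means of 188 and 1595 CPM. Oxidative phosphorylation medians were 1.10, 0.78, 0.58 and 0.60 and then 1.51, 1.17, 1.33 and 0.95. Chaperone medians were 2.00, 1.42, 1.26 and 1.39 and then 1.91, 1.51, 1.96 and 1.25, with the mitochondrial chaperone HSPD1 at means of 150.4 and 1332 CPM. Sterol synthesis medians were 1.36, 1.09, 0.84 and 1.02 at 12 h and 1.18, 0.61, 0.93 and 0.35 at 24 h, the last 2 memory values at percentiles 96.9 and 95.7. NF-kB targets had medians from 1.30 to 1.80 at 12 h and 1.08 to 1.54 at 24 h, IER3 going from a mean of 7.44 to 235.1 CPM, and the naive CD8 median at 24 h turned to -0.11 under the strict barcode filter. For these lists 12 h oxidative phosphorylation in both memory populations also lay inside the middle 95% of matched lists (percentiles 97.2 and 95.8), and the others lay above it.

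DNA replication genes came up between 12 and 24 h. At 24 h, 28 of 28 measured members were higher in naive CD4 cells and 29 of 29 in each other population (medians 3.72, 3.51, 3.99 and 2.36), against 0.53, 1.06, 0.22 and 0.29 at 12 h, where both CD8 values lay inside their matched ranges (percentiles 91.6 and 95.5). GINS2, a helicase subunit, went from 2.64, 2.58, 1.04 and 4.65 CPM at 0 h to 5.81, 13.6, 4.28 and 8.27 at 12 h and 136.4, 134.8, 155 and 98.8 at 24 h. Between 12 and 24 h, 138 genes were higher and 65 lower in naive CD4 cells, 99 and 48 in memory CD4, 441 and 191 in naive CD8 and 93 and 107 in memory CD8. The balance turned in naive CD8 cells with median-centred ratios (147 and 384) and the strict barcode filter (525 and 765). It also turned in memory CD8 cells under TMM scaling (137 and 73) and a minimum of 10 CPM (320 and 257), and in memory CD4 cells under the strict filter (138 and 145). Without turning, the naive CD4 counts were 127 and 115 under the strict filter and 70 and 46 with the mean of per-cell CPM, and those of naive CD8 were 677 and 123 under TMM scaling and 269 and 84 with that mean. PCLAF, TYMS, CDT1 and GINS2 were among the 10 highest ratios in each population. Mitosis genes followed at 24 h with medians of 3.40, 2.63, 3.13 and 0.74, UBE2C averaging 2.48 and 24.6 CPM. The resting memory CD8 library held mitosis transcripts (UBE2C 9.84 CPM against 0 to 0.0851 in the other 3 populations), and 7 of 7 measured members were lower at 12 h there (median -1.79). At a Leiden resolution of 1.0 a proliferating-like cluster of that library held 5 of 764 cells (0.654%).

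**Figure D3:**
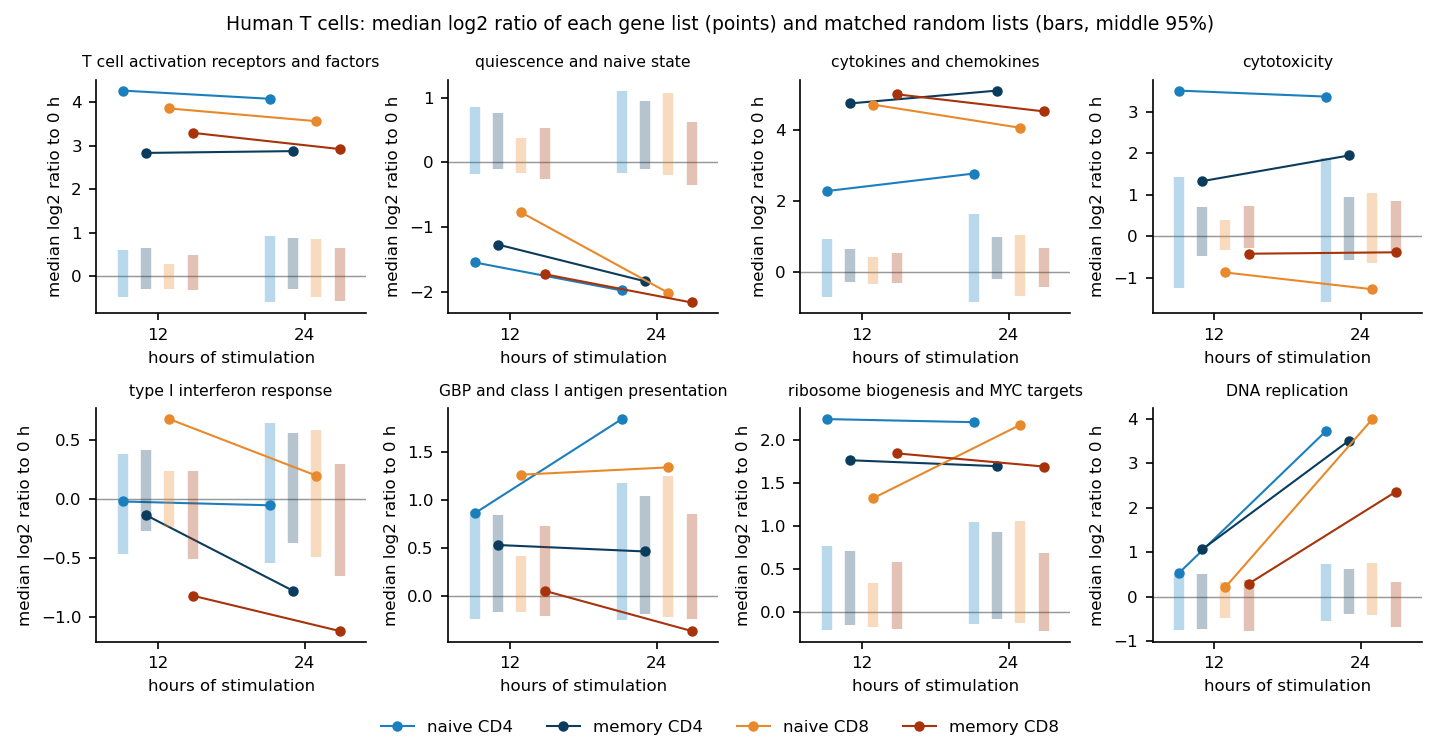
Median log2 ratio to 0 h of 8 gene lists at 12 and 24 h (points joined by lines, 1 colour per population, drawn side by side around each time) and the middle 95% of medians of matched random lists (pale bars). The activation list lies between 2.84 and 4.27 and the quiescence list between -0.77 and -2.16, while the type I interferon list runs from 0.67 in naive CD8 cells to -1.11 in memory CD8 cells. Under TMM scaling the memory CD8 values of the cytotoxicity list at both times and of the antigen presentation list at 24 h turn above 0.

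Cytokine genes were higher in every population. The type II interferon IFNG (ENSG00000111537) stayed at 0.0426, 0.861 and 0.415 CPM in naive CD4 cells at 0, 12 and 24 h. It read 0.322, 486 and 511 in memory CD4, 1.04, 344 and 115.7 in naive CD8 and 1.43, 1752 and 1047 in memory CD8 cells. IL2, the T cell growth factor, was at 94.4 and 212.6 CPM at 12 and 24 h in naive CD4, 123.2 and 173.1 in memory CD4, 0.385 and 14.1 in naive CD8 and 108.2 and 28.5 in memory CD8 cells. The chemokine CCL3 averaged 0.602 CPM at 0 h and 1100 at 24 h, and IL9, a type 2 cytokine with 0 counts at 0 h, reached 333.5 and 250.8 CPM at 24 h in memory CD4 and memory CD8 cells. Of the list, 5 of 8 measured members were higher at 12 h in naive CD4 cells, 21 of 25 in memory CD4, 15 of 17 in naive CD8 and 21 of 24 in memory CD8 (medians 2.29, 4.76, 4.72 and 5.02). At 24 h the medians were 2.78, 5.12, 4.07 and 4.54.

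Cytotoxicity genes split by gene and population. The granzyme GZMB (ENSG00000100453) was higher at 12 and 24 h in each population. It read 0.128, 15.8 and 21.8 CPM at 0, 12 and 24 h in naive CD4, 0.806, 1849 and 1737 in memory CD4, 56.5, 383 and 329 in naive CD8 and 114.8, 4200 and 4450 in memory CD8 cells. FGFBP2, a marker of cytotoxic effector cells, and the granzyme GZMK went the other way, from means of 55.2 and 138.9 CPM at 0 h to 4.92 and 15.3 at 24 h. In naive CD4 and memory CD4 cells 3 of 4 and 8 of 12 measured members were higher at 12 h (medians 3.52 and 1.33), and 4 of 5 and 8 of 12 at 24 h (3.37 and 1.95). In naive CD8 cells 12 of 18 were lower at 12 h and 13 at 24 h (medians -0.88 and -1.28). The 12 h median was 0.55 under the strict barcode filter, which left 11 cells at 0 h and 13 at 12 h. Of the resting naive CD8 cells 20.02% were in a cytotoxic effector-like cluster. In memory CD8 cells 8 of 18 were lower and 5 higher at both times (medians -0.42 and -0.39), values that turned to 0.00 and 0.14 under TMM scaling, and the mean at 12 h was 0.04.

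Interferon-response genes diverged between populations and within the list. The antiviral factor SAMD9 (ENSG00000205413) went from a mean of 124.3 CPM at 0 h to 10.99 at 24 h. At 12 h it read 81.4 CPM (95% exact Poisson interval 77.5 to 85.3) in naive CD8 and 24.6 (22.7 to 26.7) in memory CD8 cells. The antiviral GTPase MX2 went from a mean of 29.6 CPM at 0 h to 3.49 at 24 h, and the RNA sensor DDX58 from 22.04 to 5.02. At 12 h 23 of 42 measured members were higher and 4 lower in naive CD8 cells (median log2 0.67, percentile 100). The counts were 10 and 10 of 36 in naive CD4 (-0.02, percentile 57.3), 10 and 10 of 38 in memory CD4 (-0.14, percentile 11.8) and 2 and 24 of 38 in memory CD8 (-0.82, percentile 0.03). At 24 h the medians were -0.05 in naive CD4 (percentile 37.6), -0.78 in memory CD4 with 23 of 36 lower, 0.20 in naive CD8 (percentile 71.1) and -1.11 in memory CD8 with 28 of 37 lower. The means of the naive CD4 list were 0.02 and 0.05, opposite in sign to its medians. Guanylate-binding protein and class I genes had medians of 0.86, 0.53, 1.26 and 0.05 at 12 h and 1.84, 0.46, 1.34 and -0.36 at 24 h, the last turning to 0.17 under TMM scaling. Those of naive CD4 at 12 h, memory CD4 at both times and memory CD8 at 12 h lay inside their matched ranges (percentiles 97.0, 80.1, 55.6 and 21.5). TAP1, a transporter of antigenic peptides, averaged 64.8 CPM at 0 h and 337 at 24 h and was higher at both times in each population. PSME2 averaged 132.2 and 691, and GBP1 40.9 and 134.8. GBP3 went from 29.1 to 3.77. The interferon ligand and receptor list stayed inside its matched ranges (24 h medians -0.41, -0.81, -0.91 and -0.92). IFNAR1 stood at means of 44.3 and 30.8 CPM, IFNAR2 at 43.5 and 19.3, and the receptor kinase JAK1 at 301.7 and 112.0.

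Memory state genes were lower over time in memory cells, with medians of -0.60 and -0.45 in CD4 and -1.24 and -0.92 in CD8. AHNAK went from a mean of 208.1 to 15.3 CPM and KLRB1 from 211.1 to 37.0. In naive cells the medians were -1.15 and 0.01 in CD4 and -0.83 and 0.09 in CD8, the last beside a mean of -0.45. T helper lineage factors stayed inside their matched ranges (12 h 0.67, 0.37, -0.05 and 0.42, 24 h 0.64, 0.23, -0.55 and -0.30, with a mean of 0.29 in naive CD8 at 12 h), with TBX21, the master factor of type 1 helper cells, at means of 6.87 and 31.1 CPM. Eicosanoid genes had medians of 0.19, -0.53, 0.16 and -0.57 and then 0.62, -0.36, 0.41 and -0.68, of which the 12 h memory CD4 value lay outside its matched range (percentile 1.69). The naive values stood beside means of -0.12 and -0.07 at 12 h and -0.01 and -0.07 at 24 h. In that list EPHX2 stood at means of 49.8 and 10.7 CPM and PTGES3 at 228.7 and 542.4. Ribosomal protein genes had medians of -0.13, -0.22, -0.07 and -0.17 at 12 h and -0.30, -0.40, -0.37 and -0.13 at 24 h. Under TMM scaling those of naive CD4 turned to 0.17 and 0.02, memory CD4 at 12 h to 0.02, naive CD8 at 24 h to 0.03 and memory CD8 to 0.25 and 0.41. Of the coreceptors CD4 averaged 32.6 CPM at 0 h and 15.3 at 24 h, CD8A 164.6 and 93.4 and CD8B 239.5 and 86.2. Markers of other cell types were rarely at 10 CPM: of the B cell, monocyte, NK, plasmacytoid dendritic, platelet and erythroid lists at most 5 members were measured in any comparison over time. Those measured included XCL1 and IRF8, which activated T cells also express, and FCER1G at 37.1 CPM in resting naive CD8 cells and 2.32 at 24 h. Gamma delta T cell constant genes were lower, TRGC2 from a mean of 46.7 to 6.67 CPM.

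Comparing populations at matched times asked how memory differs from naive and CD8 from CD4 cells. At rest 195 genes were higher and 54 lower in memory than in naive CD4 cells and 223 and 44 in memory than in naive CD8 cells. The strict barcode filter gave 453 and 74 in CD4 and 965 and 762 in CD8, where it left 18 memory and 11 naive cells. For CD8 TMM scaling gave 127 and 45 and median-centred ratios 138 and 73. All 26 measured memory state genes were higher in memory CD4 (median log2 3.64) and 25 of 26 in memory CD8 cells (2.53). The galectin LGALS3 read 297 CPM in memory against 1.02 in naive CD4 cells and 152.7 against 4.45 in CD8, and the lectin receptor KLRB1 240 against 2.38 and 589 against 12.9. CCR7, the lymph node homing receptor, read 190.8 CPM in memory against 614 in naive CD4 cells and 115.9 against 479 in CD8, and LRRN3 21.5 against 240 and 36.8 against 326.6. At 12 h the counts were 166 and 53 in CD4 and 335 and 129 in CD8, and at 24 h 146 and 39 and 129 and 58. The CD8 counts at 12 h turned to 139 higher and 248 lower with median-centred ratios and were 469 and 451 under the strict barcode filter. At 24 h memory CD8 cells held the type 2 cytokines IL5, IL9 and IL13 at 319.5, 250.8 and 148.2 CPM against 0.0134, 0 and 0.268 in naive CD8, whose IL9 count of 0 of 74720616 UMIs allows up to 0.0401 CPM. Of the type I interferon genes at rest, 14 of 35 measured were higher and 0 lower in memory CD4 (median 0.49) and 16 of 38 higher and 1 lower in memory CD8 cells (0.45). At 12 h 17 of 35 were higher and 3 lower in memory CD4 (median 0.57), while 28 of 39 were lower and 0 higher in memory CD8 (-1.15). At 24 h 25 of 33 were lower in memory than in naive CD8 cells (-0.94) and 9 of 30 in CD4 (-0.22).

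Between CD8 and CD4 cells 51 genes were higher and 25 lower among naive and 74 and 20 among memory cells at rest. The strict barcode filter, which left 11 naive and 18 memory CD8 cells at rest, gave 1176 and 190 and then 548 and 178. TMM scaling gave 33 and 24 and then 44 and 26. CD8A read 270.3 and 387.9 CPM in naive and memory CD8 against 0.0426 and 0 in CD4 cells, and CD4 65.8 and 64.5 in CD4 against 0 and 0 in CD8 cells. Cytotoxicity genes were higher in 17 of 17 measured members in the naive CD8 library (median 4.09), with CCL5 at 645 against 2.47 CPM and NKG7 at 291.6 against 0.341. A cytotoxic effector-like cluster led by CCL5, NKG7 and GNLY held 20.02% of the cells of that library. Memory CD8 cells had a median of 3.90. At 12 h the counts were 107 and 68 among naive and 79 and 27 among memory cells (139 and 91 under the strict filter), and at 24 h 39 and 8 and 50 and 23. Those of naive cells at 12 h depended on the scaling and the barcode filter. They were 77 higher and 137 lower under TMM scaling, 77 and 81 with the mean of per-cell CPM, 126 and 129 with no barcode filter, 154 and 41 with median-centred ratios and 645 and 280 under the strict filter. The chemokine XCL1 was at 433.7 and 1751 CPM at 12 h in naive and memory CD8 against 1.26 and 31.9 in CD4 cells, and CD40LG, the helper ligand, at 2.07 and 97.0 against 132.3 and 288.6. Type I interferon genes were higher in 31 of 39 and lower in 0 in naive CD8 at 12 h (median 1.04), and lower in 17 of 34 and higher in 0 in memory CD8 (-0.60). CD8 cells were given anti-CD3 at 0.25 µg/ml and CD4 cells at 2 µg/ml, so antibody dose and lineage cannot be parted after stimulation.

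In single cells with at least 2000 UMIs, thinned to 2000, UMIs of activation genes were found in a part of each population. No library was known to hold cells that lack these genes, so the share due to free RNA was not measured, and the shares count cells with a UMI. CD69, an early activation marker, had a UMI in 4.47, 39.3 and 24.3% of naive CD4 cells at 0, 12 and 24 h (95% exact binomial intervals 3.88 to 5.12, 37.9 to 40.7 and 23.2 to 25.4%), 5.78, 28.6 and 11.3% of memory CD4, 3.64, 21.2 and 19.8% of naive CD8 and 7.02, 35.7 and 15.7% of memory CD8 cells. IL2RA, the high-affinity IL-2 receptor chain, reached 18.8, 63.1, 25.01 and 58.8% at 24 h from 1.41, 14.1, 0.0935 and 1.99% at 0 h. IFNG was found at 24 h in 15.5% of memory CD4, 5.46% of naive CD8 and 33.5% of memory CD8 cells (32.1 to 34.8%), and in 0.0667% of naive CD4 cells. GZMB was found in 31.3, 16.4 and 77.1%, and in 1.55% of naive CD4 cells. At rest 0 of 4453 naive CD4 cells had a GZMB UMI, which by the limit of 3 counts allows up to 0.0674% of cells with a UMI at 2000 UMIs (exact binomial upper bound 0.0828%), and without thinning 3 of 4462 had one. IL2 was found in 9.67% of naive CD4, 7.14% of memory CD4, 0.881% of naive CD8 and 0.922% of memory CD8 cells at 24 h, and in 3.27% of memory CD8 cells (2.57 to 4.09%) at 12 h. In resting naive CD8 cells 0 of 1070 had an IL2 UMI, which by the same limit allows up to 0.280% of cells with a UMI at this depth (exact binomial upper bound 0.344%) and sets no limit on cells expressing the gene. ISG15, an interferon-induced modifier, went from 6.51 to 16.0% in naive CD4 and from 9.91 to 16.2% in naive CD8 cells but from 17.4 to 10.4% in memory CD8 cells, with 15.1 and 14.1% in memory CD4. IFIT3 peaked at 12 h with 6.07, 6.83, 5.06 and 1.16%. Of 56 pairs of a stimulated with a resting share, 46 were higher without overlap of their intervals. Without thinning, at median depths of 5058 to 14992 UMIs, 49 were, with for example IFNG in 11.5% and GZMB in 29.8% of naive CD8 cells at 24 h against 0.260% and 3.49% of naive CD4 cells.

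**Figure D4:**
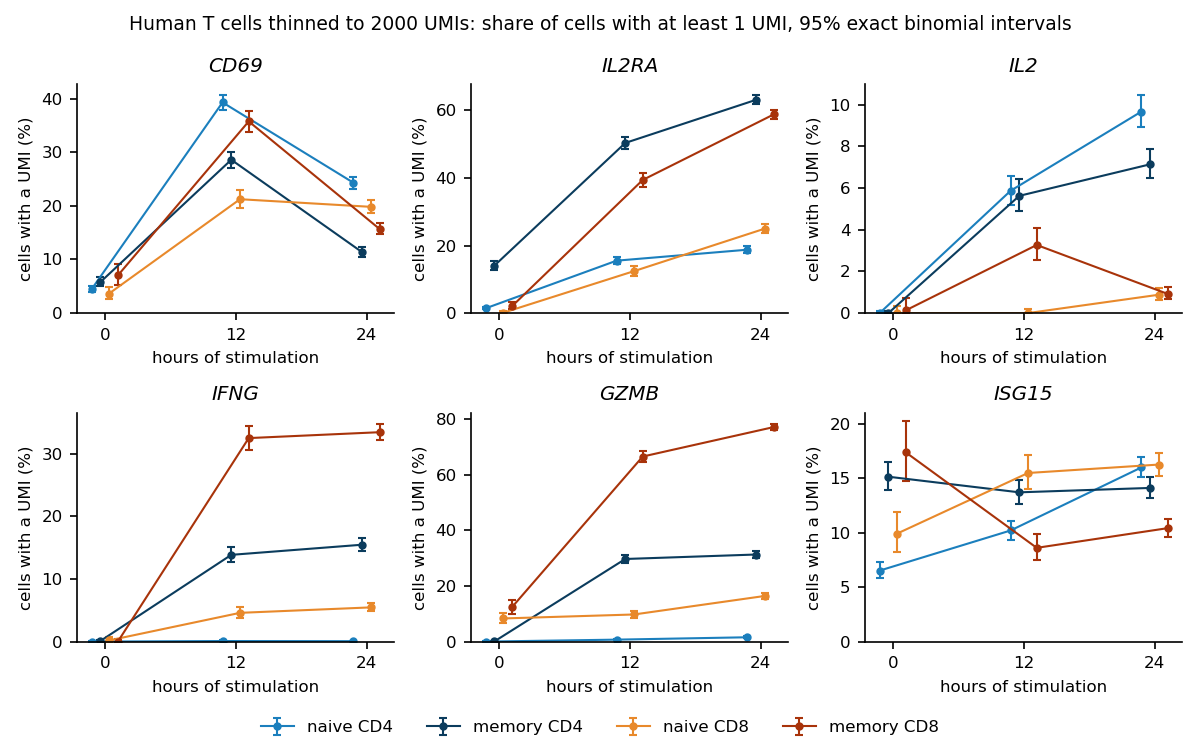
Share of cells with at least 1 UMI of 6 genes after thinning each cell with at least 2000 UMIs to 2000, in percent, against hours of stimulation, with 95% exact binomial intervals as bars and 1 colour per population. IFNG reaches 33.5% and GZMB 77.1% in memory CD8 cells at 24 h while IFNG stays at 0.0667% in naive CD4 cells, and ISG15 is higher in both naive populations and lower in memory CD8 cells at 24 h than at 0 h.

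Within libraries, clusters named from marker genes fixed beforehand showed mixed populations at rest, in naive CD4 cells under the alternative settings alone. All 4276 resting naive CD4 cells lay in clusters without a name in the main setting. A Treg-like cluster held 2.1% of them at a Leiden resolution of 1.0 and 2.1% of 4462 cells with doublets kept. In the main setting Treg-like clusters held 1.66 and 2.54% of naive CD4 cells at 12 and 24 h. Resting memory CD4 cells held 13.7% regulatory T cell-like cells (95% exact binomial interval 12.4 to 14.97%), 31.7% GZMK memory-like and 51.8% naive or central memory-like cells. Resting memory CD8 cells held 23.3% MAIT-like, 14.9% cytotoxic effector-like, 16.1% GZMK memory-like and 22.9% naive or central memory-like cells. These shares rest on the 33.6% of barcodes kept in that library. With doublets kept its GZMK memory-like and naive or central memory-like shares were 21.3 and 17.5%. At a Leiden resolution of 1.0 its naive or central memory-like share was 16.1%. In the resting naive CD8 library 20.02% (17.6 to 22.6%) were cytotoxic effector-like, the cells of a cluster led by CCL5, NKG7 and GNLY. At 24 h proliferating-like clusters held 26.3% of naive CD4, 19.8% of memory CD4 and 21.7% of memory CD8 cells, and in naive CD8 cells a cluster of 23.5% with PCLAF among its leading genes met no name. With doublets kept no cluster of naive CD4 cells at 24 h was named proliferating-like. At a Leiden resolution of 1.0 the proliferating-like shares were 7.49, 23.1 and 5.33%, the cytotoxic share of resting naive CD8 cells 15.01% and the GZMK memory-like and naive or central memory-like shares of resting memory CD4 cells 19.6 and 20.3%. A separate GZMK memory-like cluster then held 6.80% of the resting naive CD8 cells.

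The last comparison asked whether the genes called in the mouse libraries move in stimulated human cells. Human genes were matched to the lower mouse genes by symbol alone, and orthology was not checked. Of the 3 human genes so matched, MX2 was lower in all 4 populations (36.2 to 4.47, 28.6 to 3.51, 30.7 to 3.23 and 22.7 to 2.76 CPM from 0 to 24 h in naive CD4, memory CD4, naive CD8 and memory CD8 cells). ABI3 was higher (3.32 to 47.8, 7.25 to 20.9, 12.5 to 54.4 and 35.1 to 57.3 CPM), and EDN1 stayed between 0.0402 and 0.741 CPM. The medians of the 2 measured genes ran from -0.98 to 0.37 and lay inside the matched ranges in each population. These ranges were wide, for example -1.74 to 1.85 in naive CD4 cells at 24 h. As MX2 and ABI3 moved in opposite directions, their median decides nothing about a shared shift. Without the type I interferon list only ABI3 was left among the measured genes. Its log2 ratios at 12 and 24 h were 1.55 and 3.50 in naive CD4 and 0.74 and 1.41 in memory CD4 cells. They were 0.59 and 2.04 in naive CD8 and 0.28 and 0.69 in memory CD8 cells. Of these only the naive CD4 value at 24 h lay outside its matched range (percentile 98.5).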

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

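The tests of strain sequence, of interferon signalling outside the neighbourhood, of monocyte RNA and of lost barcodes, and the count of genes over other splits, were chosen only after the result was seen.

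Lists of human genes that moved in opposite directions between populations are given here for that reason alone, and no difference between populations was tested, since each group held 1 library. Cytotoxicity genes had median log2 ratios to rest of 3.52 in naive CD4, 1.33 in memory CD4, -0.88 in naive CD8 and -0.42 in memory CD8 cells at 12 h. At 24 h they were 3.37, 1.95, -1.28 and -0.39, and TMM scaling turned the memory CD8 values to 0.00 and 0.14. The strict barcode filter turned the naive CD8 value at 12 h to 0.55, with 11 cells left at 0 h and 13 at 12 h. The naive CD4 medians rested on 4 and 5 measured members and the CD8 medians on 18. Type I interferon genes at 12 h had medians of 0.67 in naive and -0.82 in memory CD8 cells. Guanylate-binding protein and class I genes at 24 h had 1.84 in naive CD4, 1.34 in naive CD8 and -0.36 in memory CD8 cells, the last turning to 0.17 under TMM scaling.

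Among the 5 mouse calls, Itsn1 and Mx2 stand 8 and 51 coding genes after Ifnar1 in human gene order and Btg3 at -76. Sequence of another strain kept around the targeted gene may contribute: of the 36 tested genes within 50 coding genes on either side, Itsn1 and Urb1 left out, 11 (30.6%) had an unadjusted p under 0.05. Of 10398 other genes 1669 (16.1%) did, an odds ratio of 2.30 (two-sided Fisher's exact test, p = 0.0365). That test takes genes as independent, while genes vary together in these libraries, so its p decides nothing. Mx2 and Btg3 lie outside the range it covered. Loss of interferon signalling stays open as well: of 60 interferon list members outside that neighbourhood, Mx1 and Mx2 left out, 11 were lower at an unadjusted p under 0.05 and 1 was higher, values seen before that decide nothing. Nothing in the tables argues against either, the labels give no strain or breeding history, human gene order only stands in for the mouse order, and reads over strain variants were not available.

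Ifnar1-/- replicates 2 and 3 stood apart from the other 4 libraries, with 2852 genes (22.4%) above and 2722 (21.4%) below all of them. A marked loss of T cells in these 2 libraries is argued against by 9 T cell genes, whose median log2 ratio to the other 4 libraries was 0.10 (-0.05 to 0.23). A small drop in the share of T cells could not be seen this way and is not excluded. RNA of monocytes or macrophages stays open, since the 2 libraries were singled out by such a marker and the rise of the list had been seen. All 9 tested markers were above the other 4 libraries in both, Cst3 at 45.1 and 52.0 CPM against 33.0 to 36.3, Lyz2 at 8.85 and 8.49 and Fcer1g at 3.98 and 3.67 against 0.734 to 1.46, although a CD4 T cell purification would remove such cells, and of these markers Tyrobp is on the NK cell list too and Cst3 and Cd68 were above 3 CPM in every library. Whether the lower DNA replication genes and higher memory genes of these 2 libraries come from the state of the cells, the animals or the culture stays open, as no label parts them from replicate 1.

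With 6 mouse libraries the 10 possible splits of 3 against 3 are too few for a share under 0.05. The genotype split called 5 genes and the highest other split 0, so 1 of 10 reached that count. The genotype split called 13 lists and the highest other 17, and 4 of 10 reached 13. The 4 splits with 13 to 17 lists, the genotype split among them, were those that kept Ifnar1-/- replicates 2 and 3 on the same side, which is the structure described above.

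The cytotoxicity list had medians of -0.88 and -1.28 at 12 and 24 h in naive CD8 libraries, although its member GZMB was higher. Under the strict barcode filter the 12 h median was 0.55. Loss of barcodes to the mitochondrial filter as the whole cause is argued against by the same list with no barcode filter, which had a median log2 ratio of -0.98 at 24 h. Fewer effector-like cells among the stimulated cells stays open. Outside all lists, 76 genes at least 4-fold higher in the effector-like cluster of the resting library had a median of -0.55 at 24 h. Of 73 measured, 36 were lower and 11 higher, and the median lay below the matched lists (-0.41 to 0.42). These genes were picked for high values in the resting library, which is also the baseline. That can pull their ratios down, so the median decides nothing. The effector-like cluster held 20.02% of the resting naive CD8 cells. At a Leiden resolution of 1.0 such clusters held 15.01% at rest and 10.5% at 24 h, and no cluster had that name at 12 h. A separate GZMK memory-like cluster then held 6.80% of the resting cells. A fall of these transcripts within the same cells, and a change of cells during culture for any other reason, were not tested and stay open.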

How the results depend on the processing

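The Xist covariate, the thinned deepest library, the fit without Ifnar1-/- replicates 2 and 3, the limit of 20% mitochondrial UMIs and median-centred ratios were chosen only after the data were seen. Unless a clause says otherwise, the cause was not tested. Depth limits what these results can show in 3 ways: the resting CD8 libraries had the fewest cells and UMIs, the strict barcode filter left 11 to 549 cells per library, and mouse genes under 1 CPM rest on few counts. The strict filter left 11 and 13 naive CD8 cells at 0 and 12 h and 18 resting memory CD8 cells. The CD8 values that turned under it rest on these few cells. The minimum of 10 CPM was not run for lists, which have a minimum of their own.

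For the mouse, 2 genes higher and 3 lower became 157 and 122 with DESeq2, 1 higher with the replicate block, 1 with limma-trend on the deposited CPM, 1 with the Xist covariate, 1 and 0 with the deepest library thinned, 5 lower with no low-count filter and 10 lower without Ifnar1-/- replicates 2 and 3. RLE size factors gave 2 and 3, the same genes. Leaving out 1 library gave 1 to 1074 higher and 0 to 959 lower, the highest of each without Ifnar1-/- replicate 1. The Ifnar1 difference turned above 0 with 1 library left out at a time (0.0017, 0.0681 and 0.0459 on the log2 scale, range -0.29 to 0.07) and was -0.32 without both Ifnar1-/- replicates 2 and 3. Of 26 lists, 13 passed by camera, 0 with an estimated correlation and 0 by fry. Camera passed 10 to 17 with 1 library left out and 7 without Ifnar1-/- replicates 2 and 3. Fry passed 13 without Ifnar1-/- replicate 1 and 0 in every other setting run for lists. The type I interferon list turned upward without Ifnar1-/- replicate 1 (camera adjusted p = 0.980), the highest value with 1 library left out, and the lowest was 1.44e-12 without replicate 2. Without Ifnar1-/- replicates 2 and 3 the cytokine (camera adjusted p = 0.282), cytotoxicity (0.846), memory (0.797), ribosomal protein (0.139) and T helper (0.792) lists turned downward. The block values come from replicate numbers that the labels do not say pair the libraries.

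For the human counts of genes under the size rule, no barcode filter, the limit of 20%, doublets left out and a pseudocount of 10 kept each of the 16 counts over time within 1.5 times. A minimum of 10 CPM moved all 16, since it admits genes of lower expression. Higher and lower genes were then 1392 and 1199 at 12 h and 1953 and 1683 at 24 h in naive CD4, 1281 and 1036 and then 1792 and 1449 in memory CD4, 694 and 501 and then 1969 and 1734 in naive CD8, and 1108 and 1484 and then 1390 and 1920 in memory CD8 cells. Between populations it gave 635 genes for memory against naive CD4, 732 for memory against naive CD8, 238 for naive CD8 against CD4 and 305 for memory CD8 against CD4 at 0 h. At 12 h these were 615, 1064, 447 and 274, and at 24 h 505, 480, 166 and 196.

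TMM scaling, which divides the stimulated libraries by smaller factors, left fewer lower genes: 240 and 358 at 12 and 24 h in naive CD4, 222 and 317 in memory CD4, 81 and 294 in naive CD8 and 209 and 246 in memory CD8 cells, the last with 1192 and 1545 higher. Memory against naive CD8 cells at rest then gave 172 genes. Median-centred ratios shifted the balance the other way by their construction, with 622 lower at 12 h and 647 higher and 883 lower at 24 h in naive CD4, 470 higher and 563 lower and then 553 and 809 in memory CD4, and 668 and 882 at 24 h in naive CD8 cells. The mean of per-cell CPM gave 241 higher genes at 12 h in naive CD8 cells. The strict barcode filter gave 1048 higher and 1222 lower at 12 h and 1514 lower at 24 h in naive CD8 and 1134 and 1325 lower in memory CD8 cells. Between populations it gave 527, 1727, 1366 and 726 genes at 0 h in the order above. At 12 h it gave 920 for memory against naive CD8, 925 for naive CD8 against CD4 and 230 for memory CD8 against CD4 cells.

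Of 159 human list medians over time, 117 lay outside the middle 95% of matched lists, which were drawn gene by gene while list members vary together. Counted as kept were those of the same sign that moved by no more than the distance from the centre to the edge of that range. Doublets left out kept all 117, no barcode filter and the limit of 20% kept 115 each, the mean of per-cell CPM 111, median-centred ratios 103, TMM scaling 93, a pseudocount of 10 78 and the strict filter 65. Those that changed sign under TMM scaling were ribosomal proteins in naive CD4 (0.17 and 0.0216 at 12 and 24 h), memory CD4 at 12 h (0.0164), naive CD8 at 24 h (0.0339) and memory CD8 cells (0.25 and 0.41), cytotoxicity in memory CD8 cells (0.0008 and 0.14) and the guanylate-binding protein and class I list in memory CD8 cells at 24 h (0.17). Under the strict filter cytotoxicity in naive CD8 cells at 12 h (0.55), NF-kB targets in naive CD8 cells at 24 h (-0.11) and ribosomal proteins in memory CD8 cells (0.0464 and 0.20) changed sign.

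At a Leiden resolution of 1.0 the cytotoxic effector-like share of resting naive CD8 cells was 15.01%, beside a GZMK memory-like cluster of 6.80%. Proliferating-like shares at 24 h were then 7.49% in naive CD4, 23.1% in memory CD4 and 5.33% in memory CD8 cells. With doublets kept the Treg-like share of resting memory CD4 cells was 15.5% and the proliferating-like share of memory CD4 cells 28.3%, while no cluster of naive CD4 cells at 24 h had that name (26.3% with doublets left out). Shares of cells with a UMI that were higher without overlap of intervals numbered 46 of 56 at 2000 UMIs, 49 without thinning and 46 at 1000. Without the type I interferon list, 1 measured human gene matched by symbol was left, ABI3. Its log2 ratios at 12 and 24 h were 1.55 and 3.50 in naive CD4 and 0.74 and 1.41 in memory CD4 cells. They were 0.59 and 2.04 in naive CD8 and 0.28 and 0.69 in memory CD8 cells.

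Over results that do not answer a comparison on their own, such as a single gene or list, 1259 values under an alternative were counted as kept. A further 76 lost the threshold, 43 gained it, 126 moved and 22 were counted as changed in sign. For mouse lists without a call a turned direction was not counted as such, so more than these 22 changed direction. Over results that do answer a comparison, 239 stayed and 93 moved.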

Other observations

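The genes named here and the grouping by Xist were chosen only after the values were seen, and no explanation is offered for them.

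Several mouse genes with large and separated differences missed the threshold of edgeR on all 6 libraries and passed it in other settings. Erdr1, a gene of the pseudoautosomal region, read 117.6, 109.4 and 179.7 CPM in wild type and 0.413, 0.614 and 3.84 in the libraries labelled Ifnar1-/- (log2 -6.38, SE 0.68, edgeR adjusted p = 0.136). Mid1, which spans the boundary of that region, read 8.62, 7.60 and 20.3 against 0.331, 0.475 and 0.632 CPM (log2 -4.66, SE 0.50, edgeR adjusted p = 0.0726). The growth factor gene Csf1 stood at 9.38 ± 1.98 CPM against 21.1 ± 1.77 in wild type (mean ± SD, n = 3, edgeR adjusted p = 0.136). Wdfy1, an adaptor of Toll-like receptor signalling, stood at 27.9 ± 2.17 against 10.3 ± 5.23 CPM (edgeR adjusted p = 0.287), and Nnt, a mitochondrial transhydrogenase, at 48.5 ± 3.22 against 32.6 ± 4.67 CPM (edgeR adjusted p = 0.287). For each of these 5 genes all 3 libraries lay on one side. DESeq2 called all 5 (adjusted p from 4.18e-14 for Mid1 to 0.0263 for Wdfy1), and edgeR without Ifnar1-/- replicate 1 called Csf1, Erdr1, Mid1 and Nnt (adjusted p from 0.00248 to 0.0311). Erdr1 also passed with limma-trend, with the Xist covariate and without Ifnar1-/- replicate 3, and Mid1 with the replicate block, with the Xist covariate and without wild type replicate 3. Csf1 passed without Ifnar1-/- replicates 2 and 3 and Wdfy1 without wild type replicate 1. The prostaglandin synthase Ptgs2 read 6.25, 9.67 and 21.3 CPM against 1.33 to 3.95 in wild type, and Foxp3, the factor of regulatory T cells, 38.4, 33.2 and 32.9 against 38.4 to 44.8.

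Without Ifnar1-/- replicates 2 and 3, the single remaining library read lower for interferon-induced genes than all 3 wild type libraries. It read 0.881 CPM of Usp18 against 11.8 to 12.2, 3.36 of Ifi27l2a against 17.3 to 20.7, 2.15 of Oas3 against 6.97 to 8.39 and 61.5 of Iigp1 against 205.2 to 233.9. In replicates 2 and 3 Usp18 (5.25 and 2.995 CPM), Ifi27l2a (11.4 and 6.11) and Oas3 (5.03 and 4.05) were lower than wild type too, while Iigp1 was higher at 338.9 and 268.4 CPM. That fit with 1 Ifnar1-/- library assumes that it varies like the wild type libraries, and these 4 genes were among its 13 calls.

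Xist, expressed in cells with more than one X chromosome, read 938.3 CPM in wild type replicate 3, 755.9 in Ifnar1-/- replicate 3 and 0.935 to 1.54 in the other 4 mouse libraries. With these 2 libraries as a covariate edgeR called 1 gene higher and 3 lower. The labels do not say whether replicate numbers pair the mouse libraries. The correlations of same-number deviations from the genotype means were 0.144, 0.0032 and 0.219. Those of different numbers ran from -0.271 to 0.101, so a structure shared by replicate number is not excluded.

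A wider set of human genes, matched by symbol to the 100 lower mouse genes with the smallest p, showed no shift beyond genes matched for expression. Of the 100 symbols, 83 were in the human files and 37 to 50 were measured per comparison. Their median log2 ratios ran from -0.39 to 0.32, each inside its matched range, with percentiles from 10.8 to 91.98.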
